A study of Homo sapiens with 21 samples.

How the data were processed

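The series measured RNA and chromatin in 786-O, an established line of human clear cell renal carcinoma cells. RNA-seq covered 9 libraries, 3 from cells infected with a control guide RNA and 3 from cells infected with each of 2 guide RNAs against JMJD6, called sg2 and sg4. The labels' treatment protocol describes siRNA transfection, while the titles and the extraction text describe infection with guides, so the RNA samples were taken as guide knockouts per the titles. ChIP-seq with an antibody to JMJD6 gave 4 libraries, of which 1 and 2 came from sequencing batch 1 and 3 and 4 from batch 2. ChIP-seq for H3K4me3, a histone mark of active promoters, gave 2 libraries in batch 2. The series also lists 6 input samples, whose values were not used here, so 15 of its 21 samples entered the comparisons. The labels call the RNA samples triplicates and do not say whether they are separate cultures, so the p-values below measure the spread between these libraries.

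For each RNA library, Salmon gave an estimated count, an effective length and a TPM per RefSeq transcript, per the file headers. The file headers name no further scaling of the estimated counts. All of these counts were whole numbers, and the step that made them so is not stated. The TPM values had been divided by effective length and scaled to a fixed sum per library, per the file headers. The submitters' processing notes list cutadapt 1.12, STAR 2.5.2b, Salmon, DESeq2, bcl2fastq 2.20.0, bedtools 2.26, MACS2 2.1.2 and the genome builds hg19 and GRCh37, without saying which tool made which file. Neither the strand setting nor the transcript annotation is given in the sources used here, so genes that overlap on opposite strands cannot be told apart. The peak lists have the narrowPeak layout of MACS2, with 1 list per library. Their deposited columns hold the fold enrichment over the peak caller's background, the −log10 p-value and the −log10 q-value. The alignment of the ChIP reads, any removal of duplicates and any role of the inputs as controls are not stated per the labels. A list of peaks says nothing of the level at positions outside the peaks, and the depth of the ChIP libraries is unknown.

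Estimated counts were summed over the transcripts of each gene. Of 60422 transcript accessions, 58031 (96.0%) matched the gene table of assembly GRCh38.p14, which was used for names only, and they belonged to 26809 genes. The unmatched accessions held between 1.33% and 1.65% of the counts of a library. Isoforms were not compared. The libraries held from 14224263 to 16300347 estimated counts each, and from 15719 to 16170 genes had a count.

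Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). All 9 libraries entered 1 quasi-likelihood fit with TMM normalisation, after filterByExpr had kept 13530 genes. Contrasts set each guide against the control, the mean of both guides against the control, and sg4 against sg2. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A change with both guides required both calls with the same sign. Because both guides share the same 3 controls, their overlap was set against 20 simulations of unchanged knockout groups with shared controls. CPM values are counts scaled by edgeR's normalised library sizes. On data simulated from the means of these libraries, with 13381 genes tested, the comparison of both guides with the control recovered 54% of genes changed by a fold of 1.25, 82% at 1.5, 86% at 2 and 98% at 3, and 9.09% of its calls were false.

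A total of 26 gene lists had been written before the data were examined, and 25 of them had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, which tests a list by itself, were the alternatives. The mean level of each list was also compared between the 3 control and 6 knockout libraries by an exact permutation test over all 84 splits, 2-sided. Besides JMJD6 and DGAT1, genes were named by a rule written before the data were examined. It took the 10 largest increases and the 10 largest decreases among genes called with both guides and with a mean log2 CPM of at least 2, and up to 3 called members per list. From sg4 against sg2 it took up to 5 genes in each direction. Most members of lists of which 5 or fewer had changed, and a few further genes that the text marks, were named after their values were seen. The rule's peaks were the 10 shared regions with the highest mean fold enrichment.

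For the peaks, coordinates are those of hg19 and are counted from 1. All JMJD6 peaks were merged into regions, and a region was called shared when it held a peak of at least 1 library of each batch. Overlap with H3K4me3 required at least 1 bp in common with a region present in both H3K4me3 libraries. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Overlap expected by chance came from 1000 random placements of the regions, uniform within their chromosomes up to the last peak. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 (figures with matplotlib 3.10.9), and recovered the known answers in simulated peak lists.

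Alternatives to these choices were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter and a stricter filter on low counts, limma-voom, glmTreat against a fold of 1.5, an offset for effective length, the replicate number as a block, fits of the compared groups alone, and leaving out each library in turn. For peaks they were a −log10 q of at least 5, a reciprocal overlap of 50%, and peaks in all 4 or in any 2 libraries. A correction for a trend with transcript length, a fit without 3 libraries in which that trend was strongest, and leaving out each H3K4me3 library were added after the data were seen. The number of a replicate did not pair libraries across groups: the correlation of 9 same-numbered pairs across genes, after group means were removed, ran from −0.141 to 0.0525. A planned comparison of JMJD6 peaks at promoters with the genes lower in the knockouts was not run, since it needs gene coordinates in hg19. For the same reason peaks are given by position, without gene names.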

Results

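The data comprised RNA-seq of 786-O renal carcinoma cells with and without knockout of JMJD6, a 2-oxoglutarate-dependent oxygenase, and ChIP-seq of JMJD6 and H3K4me3 in the same cell line. The RNA groups were a control guide, JMJD6 guide sg2 and JMJD6 guide sg4, with 3 libraries each. The libraries held from 14224263 to 15549632 estimated counts in the controls, from 14302316 to 16300347 with sg2 and from 15445425 to 16172033 with sg4. The peak lists held between 923 and 1344 JMJD6 peaks in 4 libraries, and 18745 and 18601 H3K4me3 peaks in 2 libraries.

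JMJD6 mRNA was lower in each of the 6 knockout libraries than in every control. Its level was 42.3 ± 1.88 CPM with the control guide, 16.8 ± 0.651 CPM with sg2 and 12.3 ± 1.91 CPM with sg4 (SD, n = 3 each). The mean log2 fold change of both guides was −1.56 ± 0.086 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.41e-12). The series title links JMJD6 to DGAT1, the enzyme of the last step of triglyceride synthesis, and both to lipid metabolism. DGAT1 mRNA was 39.3 ± 1.41 CPM with the control guide, 26.3 ± 0.964 CPM with sg2 and 29.7 ± 3.23 CPM with sg4 (SD, n = 3 each), and it was lower than in every control in 6 of 6 knockout libraries. It fell by 0.58 on the log2 scale with sg2 and by 0.41 with sg4, and the mean change was −0.49 ± 0.077 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.14e-04). This is a 1.41-fold decrease. It lies below the fold of 1.5 against which edgeR's glmTreat tested, so that test could not call it.

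**Figure D1:**
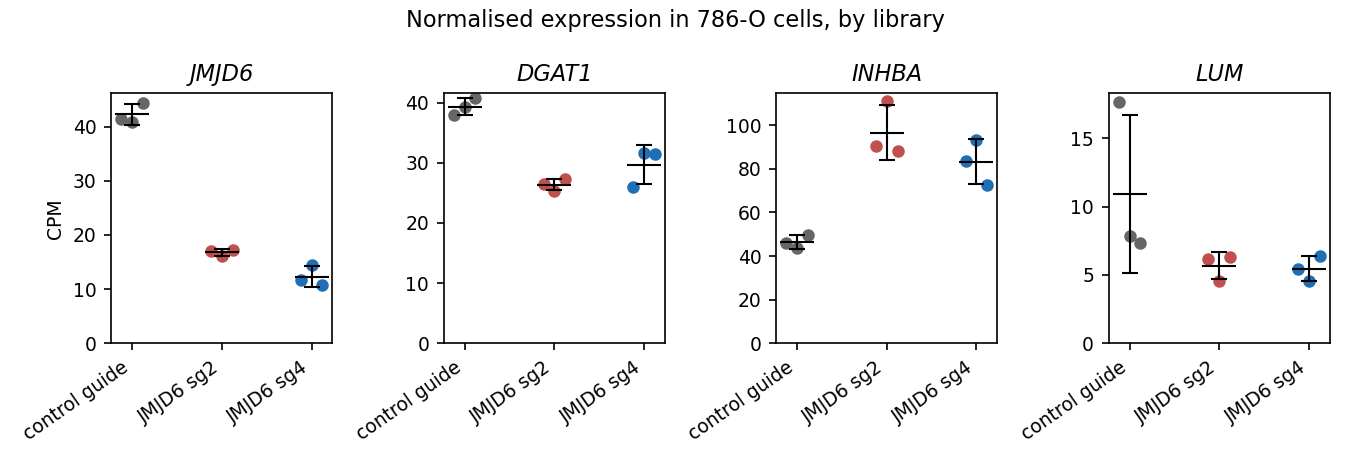
Normalised expression (CPM, y axis) of JMJD6, DGAT1, INHBA and LUM by guide, with 1 point per library and the mean and SD of 3 libraries in black. JMJD6 and DGAT1 lie below every control in all 6 knockout libraries and INHBA above, while the control mean of LUM rests on library 1, at 17.6 CPM against 7.82 and 7.32 in the other controls.

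The comparison of both guides with the control asked which genes changed with loss of JMJD6. INHBA, which encodes a subunit of activin A, rose from 46.4 ± 2.99 CPM in the controls to 96.7 ± 12.7 CPM with sg2 and 83.3 ± 10.4 CPM with sg4 (SD, n = 3 each). HBEGF, a ligand of the EGF receptor, rose by 0.86 ± 0.12 on the log2 scale, and G0S2, an inhibitor of the lipolytic enzyme ATGL, by 0.73 ± 0.10 (SE). SHISA2, TMEM258, CRISPLD2, SLC16A12, UBL5 and the ribosomal protein genes RPS29 and RPS21 completed the 10 largest increases, with log2 fold changes from 0.69 for UBL5 to 1.07 for SHISA2. After JMJD6 itself, the largest decreases were CCDC183 (−1.13 ± 0.15), SPMIP1 (−0.98 ± 0.12), LUM (−0.97 ± 0.21) and PRPF40B (−0.96 ± 0.12), given as log2 fold changes with their SE. KCP, LINC01320, RABL2A, BTBD19 and ANXA2R-AS1 followed, from −0.85 for KCP to −0.75 for ANXA2R-AS1. RABL2A has a near-identical copy with which it can share reads, and ANXA2R-AS1 cannot be told from genes on the other strand without a stated strand setting. LUM was 17.6 CPM in control 1 and at most 7.82 CPM in the other controls, and without control 1 its log2 fold change was −0.44 with an edgeR adjusted p of 0.159. BTBD19 likewise lost its call without control 3, with a log2 fold change of −0.53 and an edgeR adjusted p of 0.0592.

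In the mean of both guides, 936 genes rose and 941 fell of 13530 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With sg2 alone 677 rose and 725 fell, and with sg4 alone 629 rose and 512 fell. The direction of the calls went with transcript length. Of the 1353 genes with the shortest transcripts, 16.1% were called higher and 2.29% lower in the mean of both guides. Of the 1353 with the longest, 3.4% were called higher and 10.9% lower. Most changes were small: the median size of the called log2 changes in the mean of both guides was 0.28, and 160 of the 1877 called genes had a fold of at least 1.5. Both guides called 373 genes higher and 301 lower in common, and called 0 genes in opposite directions. After the correction for the length trend 716 genes were called with both guides, and 574 of them were among these 674. For independent guides 31.5 higher and 27.4 lower would be called in common, a value that leaves out the shared controls. In 20 simulations of unchanged groups with shared controls at most 1 gene was called in common. Since no gene was changed there, the simulations do not show how much the shared controls add to the overlap of changed genes. The changes with sg2 and sg4 correlated across genes at r = 0.681, where shared controls alone gave a mean of 0.500. Genes are not independent replicates, and the 3 controls are too few to divide between the guides. Control 1 weighed on the counts: without it 938 genes were called in the mean of both guides, 735 with sg2, 619 with sg4 and 341 with both. Without control 3 these were 1045 in the mean, 626 with sg4 and 407 with both. Without sg2 library 1, sg2 called 777 genes and both guides 409, without sg2 library 2, sg2 called 864, and without sg4 library 3, sg4 called 606.

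**Figure D2:**
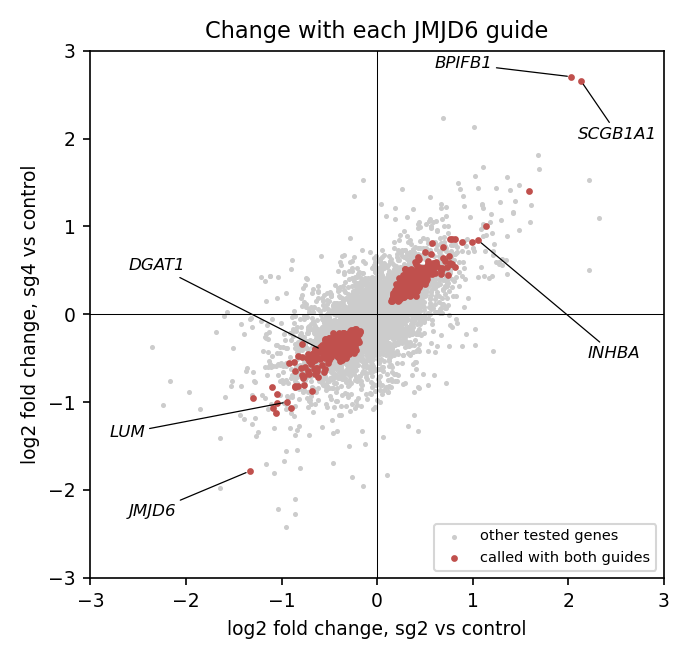
Log2 fold change of each of 13530 tested genes with sg2 (x axis) and sg4 (y axis) against the control, with the 674 genes called with both guides in red. All red genes lie in the quadrants where the guides share a direction, JMJD6 among the decreases and INHBA among the increases, and 2 genes whose counts lie mostly in control library 1, CHI3L1 and COL1A2, lie outside the axes.

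The red points farthest up are SCGB1A1 and BPIFB1, secreted proteins of the airway, which were named after their values were seen. Both have few counts: SCGB1A1 had from 4 to 24 estimated counts in a control library and from 30 to 98 in a knockout library. Whether these counts come from the cells or from other samples was not tested, so their fold changes are not read as changes in the cells.

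By camera at its preset correlation, the lists of ribosomal proteins, mitosis, DNA replication, nucleolar and MYC targets, cholesterol synthesis and oxidative phosphorylation rose. With an estimated correlation 0 of 25 lists were called. In 100 splits of the libraries, the real one included, 20 called 12 or more lists, and the other splits called a median of 7. The number of called lists thus does not exclude chance. Of 59 tested cytosolic ribosomal protein genes, which can share reads with their pseudogenes, 38 rose and 0 fell, 49 adjusted over the list alone. The median log2 fold change was 0.19, RPLP2 (0.66 ± 0.066), RPL34 (0.50 ± 0.057) and RPL38 (0.44 ± 0.068, SE) were the largest of the list, which was fixed beforehand without RPS29 and RPS21, and it had a camera adjusted p of 3.31e-26 (adjusted p = 0.247 with an estimated correlation). Short transcripts were relatively more abundant in sg4 libraries 2 and 3 and less so in control 3. After correction for that trend with length, 18 ribosomal genes rose and 1 fell, with a median of 0.09, and RPL38 was no longer called (0.11, edgeR adjusted p = 0.275). Of 33 mitosis genes 20 rose and 0 fell, 26 adjusted over the list alone, among them CCNB1 (0.34 ± 0.057), CDK1 (0.31 ± 0.064) and AURKB (0.32 ± 0.068), given as log2 fold changes with SE. Their camera adjusted p was 6.86e-14 (adjusted p = 0.247 with an estimated correlation). Of 33 genes of DNA replication 5 rose, RRM2 (0.35 ± 0.056), GINS1 (0.33 ± 0.071), RFC3 (lost without control 2, edgeR adjusted p = 0.0831), CDC6 and CDCA7, and 0 fell, 5 adjusted over the list alone, with a camera adjusted p of 6.79e-05 (adjusted p = 0.357 with an estimated correlation). Of 34 nucleolar and MYC target genes 11 rose and 0 fell, and 15 rose and 1 fell adjusted over the list alone. HSPE1 (0.52 ± 0.088), DKC1 (0.31 ± 0.056) and DDX21 (0.29 ± 0.050) were the largest, and the camera adjusted p was 1.09e-05 (adjusted p = 0.244 with an estimated correlation).

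Cholesterol synthesis genes rose as a list, with 13 of 25 higher and 0 lower, 16 adjusted over the list alone. INSIG1 (0.37 ± 0.066), SQLE (0.33 ± 0.065) and FDFT1 (0.31 ± 0.065, log2 and SE) led it, and the camera adjusted p was 4.58e-08 (adjusted p = 0.351 with an estimated correlation). Of 43 oxidative phosphorylation genes 13 rose, among them NDUFA2 (0.51 ± 0.10) and UQCRQ (0.45 ± 0.088), and 0 fell, with 15 higher and 1 lower adjusted over the list alone. The camera adjusted p was 1.44e-06 (adjusted p = 0.351 with an estimated correlation), 0.0586 after the correction for the length trend and 0.110 without control 3 and sg4 libraries 2 and 3. Triglyceride synthesis and lipid droplet genes did not move one way: G0S2 and ACSL4 rose, DGAT1 and LPIN3 fell, the other 21 were not called, and the counts adjusted over the list alone were the same 2 and 2 (camera adjusted p = 0.814). LPIN3 lost its call without control 1 (edgeR adjusted p = 0.0539) or control 3 (0.0744). In fatty acid synthesis and uptake 4 of 23 genes rose, among them FABP5 (0.52 ± 0.063), FADS2 (0.22 ± 0.045) and ELOVL5 (0.23 ± 0.050), and FADS3 fell. Adjusted over the list alone 5 rose and 3 fell, and the camera adjusted p was 0.135. In lipolysis and fatty acid oxidation ECHS1 rose and ACADVL and PPARA fell of 26, 1 and 2 also adjusted over the list alone (camera adjusted p = 0.356). ACADVL (−0.32 ± 0.066) stayed called whichever library was left out, while ECHS1 and PPARA each lost the call without any of the 3 controls or of 4 of the 6 knockout libraries, with edgeR adjusted p from 0.0511 to 0.213.

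By camera at its preset correlation, the lower lists were p53 targets, interferon-stimulated genes, renal tubule genes, 2-oxoglutarate dioxygenases, hypoxia-inducible factor targets and fibroblast markers. With sg4 alone camera called each of these lists. With sg2 alone it did not call the dioxygenases (camera adjusted p = 0.104), the hypoxia targets (0.104) or the fibroblast markers (0.0628), which does not show that the guides differ. By the exact permutation test of the library means, the unadjusted p was 0.619 for the hypoxia targets and 0.0714 for the renal tubule genes. For the other lower lists this p ran from 0.0119 to 0.0476. The mean level of the hypoxia targets lay above every control in 2 knockout libraries and below every control in 4. Of 27 p53 targets 9 fell, including FDXR (−0.38 ± 0.087) and the cell cycle inhibitor CDKN1A, and PLK2 rose, with 10 lower and 1 higher adjusted over the list alone. The camera adjusted p was 6.72e-04 (adjusted p = 0.351 with an estimated correlation). Of 38 interferon-stimulated genes 9 fell and 0 rose, and 11 fell and 1 rose adjusted over the list alone. STAT2, a transcription factor of the interferon response, fell by 0.63 ± 0.070 on the log2 scale, and the camera adjusted p was 5.21e-04 (adjusted p = 0.247 with an estimated correlation). Of 18 renal tubule genes 4 fell, among them CDH16, a cadherin of the kidney (−0.68 ± 0.087), PDZK1 (−0.32 ± 0.072) and GGT1, and 0 rose, with 4 lower and 1 higher adjusted over the list alone. The camera adjusted p was 0.00314 (adjusted p = 0.244 with an estimated correlation). Of 46 dioxygenases other than JMJD6 9 fell, among them EGLN3 (−0.32 ± 0.054), and OGFOD1 (0.31 ± 0.058) and ASPH rose, with 11 lower and 2 higher adjusted over the list alone. The camera adjusted p of 0.0197 (adjusted p = 0.247 with an estimated correlation) was 0.0680 without control 2, 0.0749 after the length correction and 0.0584 without control 3 and sg4 libraries 2 and 3. Of 24 targets of hypoxia-inducible factors, 7 fell, including NDRG1 (−0.38 ± 0.064), VEGFA and SLC2A1, and 2 rose, among them ANGPTL4, with 9 lower and 3 higher adjusted over the list alone. The camera adjusted p of 0.0342 (adjusted p = 0.712 with an estimated correlation) was from 0.0504 to 0.181 when control 1, control 2, sg2 library 1, sg2 library 2 or sg4 library 1 was left out. ANGPTL4 lost its call without control 2, control 3 or sg4 library 3 (edgeR adjusted p from 0.0513 to 0.0972).

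Of 9 tested markers of fibroblasts and pericytes COL1A2, LUM and ACTA2 fell and 0 rose, 4 adjusted over the list alone, with a camera adjusted p of 0.0197 (adjusted p = 0.351 with an estimated correlation). COL1A2 had 298 estimated counts in control 1, 45 in sg4 library 3 and at most 22 in any other library. Without control 1 the list had a camera adjusted p of 0.275 and COL1A2 an edgeR adjusted p of 0.525, while ACTA2 was still called at a log2 fold change of −0.60 (edgeR adjusted p = 0.0191). Of markers of leukocytes and endothelium 3 genes could be tested, too few for a list test: CSF1R was called higher, CD68 lower and 1 was not called, and adjusted over the list alone 1 was higher and 2 lower. CSF1R lost its call without control 1 or 3 and CD68 without control 3 (edgeR adjusted p = 0.0527, 0.0506 and 0.249).

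**Figure D3:**
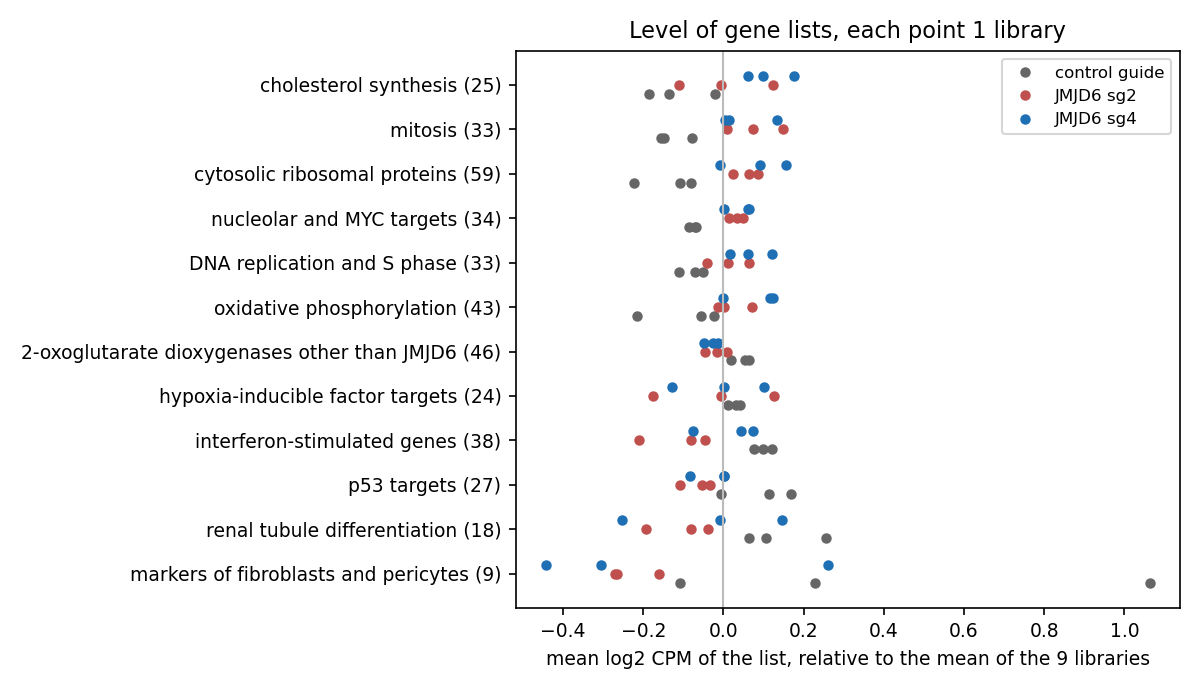
Mean log2 CPM of the genes of each called list (x axis, relative to the mean of the 9 libraries), with 1 point per library and the number of tested genes in parentheses. The ribosomal protein, mitosis and nucleolar lists lie above every control in 6 of 6 knockout libraries, and the fibroblast list is highest in a single control library.

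The other lists were not called by camera in the mean of both guides with all 9 libraries. In some fits with a single guide or fewer libraries, the NF-kB and homologous recombination lists gained a call as higher, and the ATF4 and antigen presentation lists as lower. Glycolysis had 4 of 23 genes higher, including PGK1, and PFKL (−0.46 ± 0.048) and SLC2A1 lower, 6 and 4 adjusted over the list alone (camera adjusted p = 0.548). The unfolded protein response had 3 of 23 higher, MANF, XBP1 and SSR1, and SYVN1 lower, 3 and 2 adjusted over the list alone (0.244). The ATF4 and amino acid response had 2 of 27 lower, NUPR1 (−0.42 ± 0.067) and SHMT2, and also 2 adjusted over the list alone (0.287). In homologous recombination repair 1 of 31, BRCA2, was higher and 0 adjusted over the list alone (0.271), and in antigen presentation 1 of 18, HLA-F, was lower, also adjusted over the list alone (0.287). The NF-kB list had 2 of 24 higher, IL11 and CSF1, also adjusted over the list alone (0.188). The mesenchymal list had 5 of 30 higher, among them SNAI2 (0.34 ± 0.076), THBS1, SPARC and TGFBI, and 4 lower, COL1A2, ACTA2, MMP2 and FN1, 6 and 5 adjusted over the list alone (0.548). Its median log2 fold change was 0.06 and its camera direction up, but its mean was −0.16. That mean includes COL1A2 at −4.35, which had 298 of its 375 estimated counts in control 1. Without control 1 COL1A2 was at −1.19 and was not called (edgeR adjusted p = 0.525). In splicing factors 4 of 48 were higher, SNRPB, SRSF7, SRPK1 and SRSF6, and 3 lower, CLK2, LUC7L3 and RBM10, 5 and 6 adjusted over the list alone (0.466), and in transcription elongation 2 of 32 were higher, ELL2 (0.34 ± 0.066) and MYC, and AFF1 lower, 4 and 4 adjusted over the list alone (0.927). The NRF2 list had 4 of 27 higher, including PRDX1 and TXN, and ABCC3 and EPHX1 lower, 4 and 2 adjusted over the list alone (0.392). Among these genes MANF, XBP1, SYVN1, SHMT2, BRCA2, HLA-F, IL11, CSF1, SNRPB, CLK2, LUC7L3, MYC and AFF1 each lost the call when a single control library, and for some of them a single knockout library, was left out, with edgeR adjusted p from 0.0505 to 0.259. By the exact permutation test of the library means, the ribosomal, mitosis, nucleolar and dioxygenase lists reached the smallest p that 84 splits allow, 0.0119, and after adjustment over 25 lists the lowest value was 0.0744.

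The guides were also set against each other. FXYD2, a regulator of the sodium pump in the kidney, was 33.3 ± 3.82 CPM with sg4 and 22.3 ± 0.561 CPM with sg2 (SD, n = 3 each), against 33.5 ± 2.14 CPM in the controls. DPP7, C3, SOD2, SERPINA1 and SDC1 were also higher with sg4 than with sg2, and DLC1 and MTUS1 were lower, with log2 differences from −0.38 to 0.58. SDC1 lies outside the naming rule and was named after its value was seen. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 8 of 13530 genes differed between the guides, 1337 had an unadjusted p under 0.05, and 0 of the 8 had a fold of at least 1.5. The call was 0 genes without sg2 library 1, sg4 library 2 or sg4 library 3, 3 without control 1, 4 without sg2 library 3, 14 without sg2 library 2 and 49 without sg4 library 1.

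JMJD6 ChIP-seq asked where on chromatin the protein was found and whether those places carried the promoter mark H3K4me3. The strongest shared region lay on chromosome 15 from 45003279 to 45003953, with a mean fold enrichment of 92.7 ± 4.80 (SD, n = 4). Next were chromosome 10 from 111970703 to 111971461 (91.1 ± 10.7) and chromosome 1 from 151319432 to 151320278 (78.4 ± 12.8). The other 7 of the 10 strongest regions lay on chromosomes 3, 7, 11, 12, 17 and 19, with 2 of them on chromosome 17, and had mean fold enrichments from 65.4 to 77.8. All 10 had a peak in each of the 4 libraries and overlapped H3K4me3. The peaks of the 4 libraries merged into 1689 regions, of which 1025 (60.7%) were shared by both sequencing batches, 420 were found in batch 1 alone and 244 in batch 2 alone. A peak in all 4 libraries was present in 685 regions.

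Of the 1025 shared regions, 815 overlapped H3K4me3, or 79.5% (exact 95% interval 76.9 to 81.9%). Random placement gave a mean of 18.6 regions and at most 37, with a permutation p of 0.000999, the smallest that 1000 placements can give. The placements were uniform along each chromosome, so this p excludes uniform placement only. It does not tell how the overlap compares with that of other proteins at promoters. By library the overlap was 76.9%, 69.0%, 79.0% and 80.0% of peaks, or 73.0 ± 5.55% in batch 1 and 79.5 ± 0.708% in batch 2 (SD, n = 2 each), too few libraries to test the batches against each other. Regions found in all 4 libraries overlapped H3K4me3 in 82.8% of cases and regions found in 1 library in 57.1% (Fisher's exact test, 2-sided, p = 1.37e-23). Conversely, 825 of 16218 H3K4me3 regions, or 5.09%, held a JMJD6 region. Chromosome 19 held 149 shared JMJD6 regions, 14.5% of them against 7.08% of H3K4me3 regions (Fisher's exact test, 2-sided, Benjamini-Hochberg adjusted p = 7.87e-14 over 38 chromosomes and contigs). Chromosome X (1.27% against 3.20%, adjusted p = 0.00330), chromosome 4 (1.85% against 3.84%, adjusted p = 0.00774) and chromosome 15 (1.66% against 3.28%, adjusted p = 0.0298) held fewer than H3K4me3 regions did, by the same exact test. The unplaced contig gl000220 held more, with 3 regions (0.293% against 0.0247%, adjusted p = 0.0465 by that exact test). These tests by chromosome took regions as independent. They also took the JMJD6 and H3K4me3 regions as separate sets, although 815 of the 1025 overlapped. ChIP-seq of JMJD6 knockout cells is not among the samples, so peaks that depend on the antibody rather than on JMJD6 cannot be recognised.

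**Figure D4:**
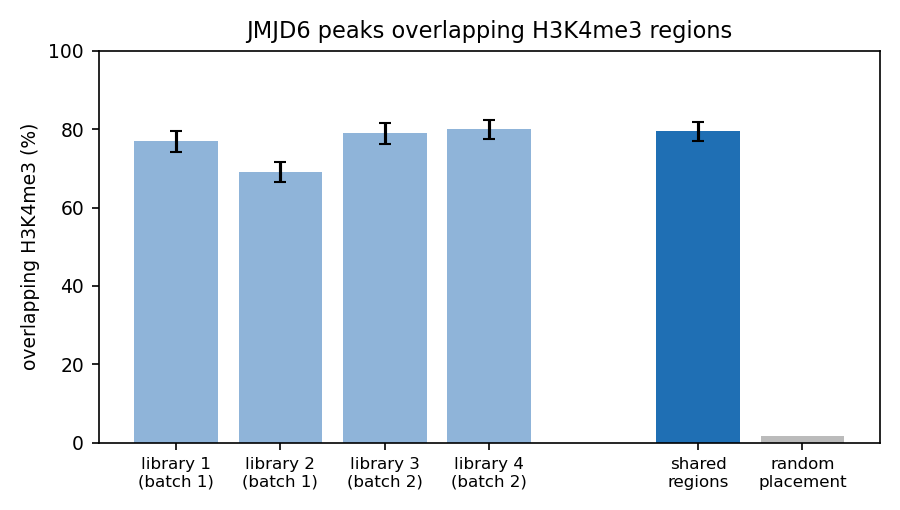
Percent of JMJD6 peaks in each library, and of the 1025 regions shared by both batches, that overlap H3K4me3 (y axis), with exact 95% intervals for counting error, and the mean of random placements. The libraries lie between 69.0% and 80.0% and the shared regions at 79.5%, against 1.81% for random placement.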

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

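The length-trend correction, the fit without control 3 and sg4 libraries 2 and 3, and the tests of the lysosomal genes and of the interval on chromosome 6 were chosen only after the results were seen.

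A total of 8 genes differed between the guides by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which put them here, but 10 splits of 6 libraries are too few to exclude chance. The log2 differences, sg4 minus sg2, were 0.58 for FXYD2, 0.45 for DPP7, 0.44 for C3, 0.39 for SOD2, 0.39 for SERPINA1, 0.28 for SDC1, −0.34 for DLC1 and −0.38 for MTUS1. The adjusted p ran from 0.0150 to 0.0388, and all 8 lost the call whenever sg2 library 1, sg4 library 2 or sg4 library 3 was left out. As lists, cholesterol synthesis (camera adjusted p = 4.56e-04), interferon-stimulated genes (0.00549), NF-kB and inflammatory cytokines (0.00549), antigen presentation (0.00604), DNA replication (0.0191), oxidative phosphorylation (0.020) and glycolysis (0.0418) were higher with sg4 than with sg2, and the ATF4 list (0.0418) was lower. With an estimated correlation the unadjusted p of these 8 lists lay between 0.0774 and 0.393. This contrast had the strongest trend with transcript length, with a Spearman correlation of −0.228 across genes. After the length-trend correction oxidative phosphorylation (camera adjusted p = 0.699) and glycolysis (0.132) were no longer called, while the other 6 lists kept their direction and their call.

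Genes of lysosomal enzymes and membrane proteins were lower in the knockouts, in a list of 40 chosen after the data were seen. Of 39 tested, 14 fell, among them GAA (−0.74 ± 0.066), DPP7 (−0.56 ± 0.064), TCIRG1 (−0.58 ± 0.070) and CTSD (−0.24 ± 0.042, log2 and SE), NPC2 rose, and 9 fell with both guides. The values argue against the length trend between libraries: after its correction the median log2 fold change was −0.096 ± 0.0090 (SE), against −0.10 ± 0.012 before. This SE comes from the spread of the list's mean level between libraries of a group, and is not an SE of the median. The correction was fitted to the same libraries, which can narrow that spread. The level of the list was lower than in every control in 6 of 6 knockout libraries (exact permutation p = 0.0119, the smallest that 84 splits give), and camera with an estimated correlation gave p = 0.00153. Because the list was chosen after its genes were seen lower in these libraries, these p-values add no support for an effect of the knockout, and other causes than the length trend stay open.

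Cytosolic ribosomal protein genes were higher in the knockouts, with a median log2 fold change of 0.19 ± 0.047. Here too the SE comes from the spread of the list's mean level between libraries of a group. The 3 libraries with the strongest length trend, control 3 and sg4 libraries 2 and 3, were not the whole source, since without them the median was 0.116 ± 0.022 with 15 genes higher. After correction for the length trend between libraries the median was 0.091 ± 0.0096, with 18 genes higher and 1 lower. Camera at its preset correlation still called the list. The trend as fitted thus left part of the increase and may account for another part. Because it was fitted to the same libraries, the smaller SE does not show how well the trend was removed. Before correction, camera with an estimated correlation did not call it (adjusted p = 0.247). The list was higher than in every control in 6 of 6 knockout libraries, exact permutation p = 0.0119 (0.0744 adjusted over 25 lists), which is consistent with an effect of the knockout, while GC content and reads shared with pseudogenes were not tested and stay open.

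JMJD6 regions were concentrated between 29 and 33 Mb of chromosome 6, which holds the major histocompatibility complex, with 26 of 1025 shared regions (2.54%) against 0.561% of H3K4me3 regions, 4.52 times the 5.75 expected (Fisher's exact test, 2-sided, p = 3.89e-09). Fisher's test took regions as independent and the JMJD6 and H3K4me3 regions as separate sets, although most shared regions overlapped H3K4me3. The density of H3K4me3 regions does not account for the concentration: of 1000 random draws of as many H3K4me3 regions, 0 had an excess as large in any 4 Mb window. The interval was found among regions that by definition hold a peak of both batches, so 1 library or 1 batch cannot be its source. For the same reason, the share above that of H3K4me3 regions in 4 of 4 libraries is no separate test. Among 1620 windows it ranked 3, behind windows at 48 to 52 and 46 to 50 Mb of chromosome 19, and 14 of its 26 regions overlapped H3K4me3, against 79.5% of all shared regions. No biological explanation was tested, an effect of the antibody stays open without ChIP-seq of knockout cells, and the antigen presentation list was not called in the RNA of all 9 libraries (camera adjusted p = 0.287) but was called lower without control 3 (0.0353) and without control 3 and sg4 libraries 2 and 3 (0.00127).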

How the results depend on the processing

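The length-trend correction, the fit without control 3 and sg4 libraries 2 and 3 (which leaves 1 sg4 library, assumed to vary like the other groups) and leaving out H3K4me3 libraries were chosen only after the data were seen. The genes named by the rule and the called lists kept their direction; other genes, some of them named in the text, were only counted. Camera's direction turned for some uncalled lists, and the cause was not tested. With sg2 alone this was glycolysis (median log2 fold change 0.049) and transcription elongation (0.0027), and after the length-trend correction transcription elongation (−0.014). Without control 3 and sg4 libraries 2 and 3 it was glycolysis (−0.0082), NF-kB (−0.041), the mesenchymal list (−0.018) and transcription elongation (−0.011). Of single libraries, it turned for the mesenchymal list without control 3 (0.024, with a range of 0.018 to 0.073 over all 9) and for transcription elongation without control 2, control 3, sg2 library 1 or sg4 library 3 (range over all 9, −0.039 to −1.65e-04). Some uncalled lists gained a call: NF-kB, higher, with sg4 alone (camera adjusted p = 0.0174) and without control 1, sg2 library 2 or sg4 library 1 (0.0149 to 0.0442), and ATF4 and antigen presentation, lower, without control 3 (0.0284 and 0.0353). Without control 3 and sg4 libraries 2 and 3, ATF4 (8.47e-04) and antigen presentation (0.00127), lower, and homologous recombination (0.0239) and fatty acid synthesis (0.0265), higher, gained one. JMJD6 kept its call under all alternatives, with log2 fold changes from −1.63 to −1.51, and DGAT1, from −0.56 to −0.44, under all but glmTreat, where its value of −0.49 was not past a fold of 1.5. That test called 2 genes with sg2, 1 with sg4, 1 in their mean, 1 with both and 0 between the guides. Most called changes were below its threshold, but 160 of the 1877 genes called in the mean had a fold of at least 1.5. Leaving out single libraries gave 735 to 1595 genes for sg2, 606 to 1227 for sg4, 938 to 1878 for their mean, 341 to 628 with both guides and 0 to 49 between the guides. Without control 3 and sg4 libraries 2 and 3 there were 358 genes for sg4, 1116 for the mean, 272 with both and 0 between the guides, from fewer libraries. Between the guides DESeq2 called 38 genes, no filter on low counts 72, the replicate block 2 and the length-trend correction 13, against 8; the cause was not tested. Of 25 lists, camera called 12 (6 higher), camera with an estimated correlation 0 and fry 6 (3 higher). The camera settings differ in the correlation between genes, while fry asks another question, whether a list changed by itself. With camera at its preset correlation, leaving out single libraries gave 10 to 14 lists. Of 84 genes named by the rule in the mean of both guides, 46 kept their call under every alternative except glmTreat and 38 lost it in at least 1, 27 of them without control 3 and sg4 libraries 2 and 3, and among single libraries most often without control 1 (21) or control 3 (21). Shared JMJD6 regions numbered 685 to 1108 and their overlap with H3K4me3 was 77.8 to 82.8%. Comparisons of JMJD6 peaks at promoters with gene calls, and their 5 alternatives, were not run.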

Other observations

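The test of long noncoding genes and the choice of the genes described here were made only after the data were seen; the splits of the libraries were planned.

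FOS, EGR1, FOSB and NEAT1 were lower in the knockouts. FOS fell from 89.4 ± 2.36 CPM in the controls to 57.4 ± 6.55 CPM with sg2 and 64.8 ± 3.1 CPM with sg4, and EGR1 from 219.3 ± 26.2 to 154.8 ± 12.9 and 182.3 ± 10.2 CPM (SD, n = 3 each). FOSB had a log2 fold change of −0.74 ± 0.12 and the nuclear noncoding RNA NEAT1 of −0.70 ± 0.11 (SE), and each of these 4 genes was called with both guides by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The controls spread widely for FOSB (60.5 ± 16.7 CPM) and NEAT1 (585.5 ± 141.8 CPM, SD, n = 3 each). FOS lay below every control in 6 of 6 knockout libraries, and EGR1, FOSB and NEAT1 each in 5. MALAT1, another nuclear noncoding RNA, had a log2 fold change of −0.10 ± 0.12 (SE) and was not called.

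Transcripts that are abundant in other tissues appeared at low counts. CHI3L1, COL1A2, COL3A1 and DCN, genes of connective tissue, held 1173 estimated counts together in control 1, 208 in sg4 library 3, 76 in control 2 and at most 12 in each other library. Their counts kept similar proportions across libraries: control 1 held between 75.2% and 79.5% of the counts of each gene, sg4 library 3 between 12.0% and 16.2%, and control 2 between 3.59% and 5.87%. A set of 7 airway genes (SCGB1A1, BPIFB1, BPIFA1, MUC5B, SFTPA1, SFTPA2 and SFTPB) had another distribution, with 8, 29 and 78 counts in the controls, 193, 135 and 70 with sg2 and 243, 249 and 123 with sg4. SCGB1A1 and BPIFB1 were called higher with both guides, at log2 fold changes of 2.40 ± 0.44 and 2.37 ± 0.44 (SE, edgeR adjusted p = 6.27e-04 and 6.44e-04), and CHI3L1 was called lower in their mean at −4.89 ± 0.95 (edgeR adjusted p = 0.00103). Whether these counts come from the cells or from RNA or reads of other samples was not tested, so the fold changes are not read as changes in the cells.

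Long noncoding genes were called lower more often than higher in the mean of both guides, 39 against 12 of 798 tested. Their lower share was 4.89%, against a mean of 3.57% for protein-coding genes drawn at the same level, and 300 of 10000 such draws had a share as large. The direction was chosen after the pattern was seen in the same data, and genes were drawn as if independent. The draws thus do not exclude the level of the genes as its source. Over all protein-coding genes tested, 7.10% were called lower and 7.34% higher. The draws of protein-coding genes were themselves called lower more often than higher, at means of 3.57% and 1.92%, and 2337 of them had as few higher calls as the 1.5% of the long noncoding genes.

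Other splits of the 9 libraries into groups of 3, 3 and 3 were drawn, 100 of 840 with the real one. As many genes as in the mean of both guides (1877) were called in 2 of them, the real one included. The highest other count, 1909, came from a split that kept the real controls together, and among 96 splits with other controls the highest was 112. As many genes with both guides (674) were called in 1, the real one, with 653 as the highest other. That split also kept the real controls together, and among the 96 splits with other controls the highest was 5. A random grouping of these libraries is thus an unlikely source of either count. The splits cannot tell the knockout from any other difference between the control and knockout libraries. As many lists as the real 12 were called in 20, and the highest other was 15, so chance cannot be excluded for the number of called lists. For sg2 (1402 genes, highest other 0), sg4 (1141, highest other 1) and the difference between the guides (8, highest other 1), the 10 splits of 6 libraries are too few for a share under 0.05, and the real split alone reached its count, 1 of 10 in each.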
